A study of Xenopus laevis with 16 samples.

How the data were processed

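RNA was measured in 16 libraries of Xenopus laevis embryonic tissue, all collected at stage 12. Animal caps are the pluripotent ectoderm at the top of the blastula; left alone they form epidermis. There were 4 libraries of untreated caps (controls 1 to 4), 3 of caps taken apart into single cells (dissociated 1 to 3), and 1 each of caps from embryos injected with mRNA for BMP4, Chordin, Wnt8, Cerberus, FGF8, Xnr2, or Wnt8 together with Xnr2. The last 2 libraries came from embryos divided into a dorsal and a ventral part. Per the labels' protocols, mRNA was injected in early cleavage, caps were explanted at stage 9 and the dorsal and ventral parts at stage 10, and polyadenylated RNA was made into TruSeq libraries and read as single 100-bp reads on an Illumina HiSeq sequencer. The labels name control 1 as the control of dissociated 1, BMP4 and Chordin, control 3 as that of dissociated 3, Wnt8 and Cerberus, control 4 as that of FGF8, Xnr2 and Wnt8 plus Xnr2, and control 2 as that of dissociated 2. These 4 families are called control sets here. Nothing in the labels says whether replicates came from separate clutches, so p-values measure the spread between these samples, part of which may be technical.

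Values were RPKM (reads scaled to transcript length and mapped reads), which the authors computed for transcripts of the JGI9.1 genome, per the file headers. The submitters' notes name TopHat2 2.09 and DESeq. Which step each served, the annotation release and the counting rule are not given in the sources used. One deposited table lists 43646 transcripts in controls 1 to 3 and dissociated 1 to 3 without a filter found on its values. Tables pairing 1 treated library with its control, or dorsal with ventral, leave out transcripts with a mean under 1 RPKM, per the file headers. One setting Cerberus, Chordin and Wnt8 beside control 2 lists some below it. A gene missing throughout has no value and was not set to 0. The authors also deposited fold changes (ratios of 2 RPKM columns) and a p-value for dissociation whose test is not named. Neither was used for a result, but the text ends with 1 check of the ratios. Transcript names are those of the files, where .L and .S mark the homeologous copies of the allotetraploid genome. Of 25756 numbered models, 14803 have a human symbol, assigned per the file headers by protein comparison. They are given below by symbol and number. L and S copies and duplicated models resemble each other, and how reads were divided is not given in the sources used. Differences between copies of 1 gene are uncertain. No genome of this build was used, so no coordinates are given.

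Because an RPKM value is a whole number of reads divided by length and depth, reads could be recovered: for 31343 of 31587 transcripts with at least 3 values above 0 (99.23%), a single length made the values whole to within 0.01 reads. The recovered depth ran from 25408438 to 46522450 mapped reads per library. Recovered reads served for counting intervals and an added test. Main tests used RPKM.

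Tests were run with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend and Benjamini-Hochberg adjustment over all transcripts tested. Calls have an adjusted p under 0.05. Tested transcripts average at least 1 RPKM, over 6 libraries for dissociation and over the treated library and its own control for an injection. A transcript near 0 in controls is thus tested only where the treatment raises it, which pushes list medians and shares raised upward. Fold changes are on this log2(RPKM + 1) scale, which understates the change of genes with low values. Dissociation was tested with 3 libraries on each side. Each injected library was set against controls 1 to 4, the spread being estimated from the control and dissociated libraries; the lone treated library is assumed to vary like them, and its log2 ratio to its own control is given as well. The design put every cap library in 1 fit, but other lone libraries add nothing to the spread and were left out. It also left the filter open, and the authors' minimum of 1 RPKM was taken after the tables were seen. Dorsal against ventral, and Wnt8 plus Xnr2 against Xnr2, are comparisons of 1 library with 1: no p-value is given, genes are counted at a ratio of at least 4-fold on log2(RPKM + 1) with at least 5 RPKM in the higher library, and 95% intervals of a ratio come from the exact binomial interval of the recovered reads. Such intervals cover counting error only.

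Transcripts named in control 4 and its treated libraries without a single read in the 6 libraries of the full table were left out of the 3 fits that use control set 4: 894 for FGF8, 948 for Xnr2 and 961 for Wnt8 plus Xnr2. This was decided after the values were seen, since many appear to be other names for the same genes. The closing section gives results with them kept.

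Gene lists, 17 in number, were fixed before the data were examined: organizer and dorsal mesoderm, pan-neural, anterior neural and cement gland, posterior axis, BMP targets and ventral genes, epidermis, ciliated cell and ionocyte, Wnt targets, pan-mesoderm, endoderm, FGF-MAPK feedback, Nodal targets, neural crest and border, muscle and blood, immediate-early and stress, cell adhesion and matrix, and housekeeping reference. Several genes stand in more than 1 list. Lists were tested with camera in limma on the moderated statistics (preset correlation between genes 0.01), leaving out the injected gene, with adjustment over 136 tests, 17 lists in 8 comparisons; camera was repeated with the correlation estimated from the libraries. The repeat needs a value in every library, so in 42 of the 136 tests it covered fewer transcripts. For comparisons of 1 library with 1, a list's median log2 ratio is placed among 10000 random lists matched on size and mean expression. These lack the correlation between list members, so percentiles are ranks, not p-values. The genes named were set by a rule written before the data were examined: the injected gene, up to 10 transcripts each way with the largest change among calls with at least 5 RPKM in the higher group, a gene symbol and the same direction against each matched control, and members of the lists. The result of 1 gene that this rule names is not reported here.

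The labels pair controls 1, 2 and 3 with dissociated 1, 2 and 3. Deviations of same-numbered libraries from their group means correlated across transcripts at 0.584, 0.391 and 0.628, against -0.48 to 0.131 for different numbers. The control set as a block was an alternative; values with it stand beside a result where it changes a call or moves a count by over 1.5 times.

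Responses were compared across transcripts as log2 ratios to matched controls, mostly between treatments that share no control library. Where they share one, unchanged libraries against it were simulated with 100 draws. The scripts were tested on simulated data with 15830 transcripts. With 3 libraries against 3, 4% of 2-fold, 28% of 4-fold, 50% of 8-fold and 62% of 16-fold changes were recovered, with 3 of 75 calls false. With 1 against 4 the shares were 0%, 10%, 32% and 46%, with 0 of 44 calls false. These values are not rates for the real libraries, where those of 1 control set deviated together. The list test called 52.5% of lists shifted by 0.5 in the moderated statistic, 100% of those shifted by 1, and 0% of unshifted lists. The simulated statistics were independent between transcripts, so these shares do not hold for lists of correlated genes. Other alternatives were quantile normalization, no filter, pseudocounts of 0.1 and 5, summed L and S copies, each library left out in turn and, for dissociation, a spread shared with all caps or control 4 added. Median scaling, voom on recovered reads and a 5 RPKM minimum across transcripts were chosen after the data were seen. Voom left out control 4 for control sets 1 and 3. Data handling and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.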

Results

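The libraries ask how dissociation, growth factors and antagonists change the cap transcriptome, and how this compares with dorsal and ventral embryo parts. Control caps gave 4 libraries, dissociated caps 3, and each injection and embryo part 1. The injected amounts were 200 pg of BMP4 mRNA, 400 pg of Chordin, 16 pg of Wnt8, 400 pg of Cerberus, 200 pg of FGF8, 200 pg of Xnr2, and 16 pg of Wnt8 with 200 pg of Xnr2. Depth was lowest in the ventral library and highest in control 3. Means and SD below are RPKM over 3 control and 3 dissociated libraries, or, for the injections, over those of the 4 controls that list the transcript. A treated library without replicates has no SD. Log2 changes carry the standard error of the fit (SE), adjusted p-values are limma's over all transcripts tested, and list p-values are camera's, adjusted over 136 tests.

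Transcripts of the injected BMP4, Chordin, Cerberus, FGF8 and Wnt8 mRNAs were higher in their libraries than in matched controls. The double injection could not be checked for Wnt8. The transcript bmp4.S read 1762 RPKM in the BMP4 library and 37.7 in its control. CHRD (Xelaev18029538m) read 2581 RPKM after Chordin injection against 0.661, cer1.S 6208 after Cerberus against 0.056, and fgf8.L 170 after FGF8 against 0.332. For wnt8a.L the values were 12.9 RPKM after Wnt8 and 0.463 in the control. The Xnr2 gene nodal2.L read 3.29 RPKM after Xnr2 and 12.5 after Wnt8 plus Xnr2, against 0.037 in control 4, and these values cannot tell injected from endogenous transcripts. In the double injection wnt8a.L read 77.0 RPKM, but it stood at 101 after Xnr2 alone, and wnt8a.S read 45.7 and 94.7.

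Untreated caps were not alike in every gene group. Across 14259 transcripts, log2 values of controls 2, 3 and 4 correlated at 0.944 to 0.95, and those of control 1 with the others at 0.843 to 0.901. In control 1, the list of BMP targets and ventral genes averaged 4.15 on the log2(RPKM + 1) scale against 5.44 to 5.86 in the other controls. The epidermis list averaged 5.18 against 5.997 to 6.181, and the ciliated cell and ionocyte list 3.10 against 4.93 to 5.40. The pan-neural list was higher, at 4.80 against 3.20 to 3.53. The endoderm list averaged 0.86 in control 1 against 2.62 to 2.93. Control 1 is the matched control of BMP4, Chordin and dissociated 1, and among the controls of all 8 comparisons.

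**Figure D1:**
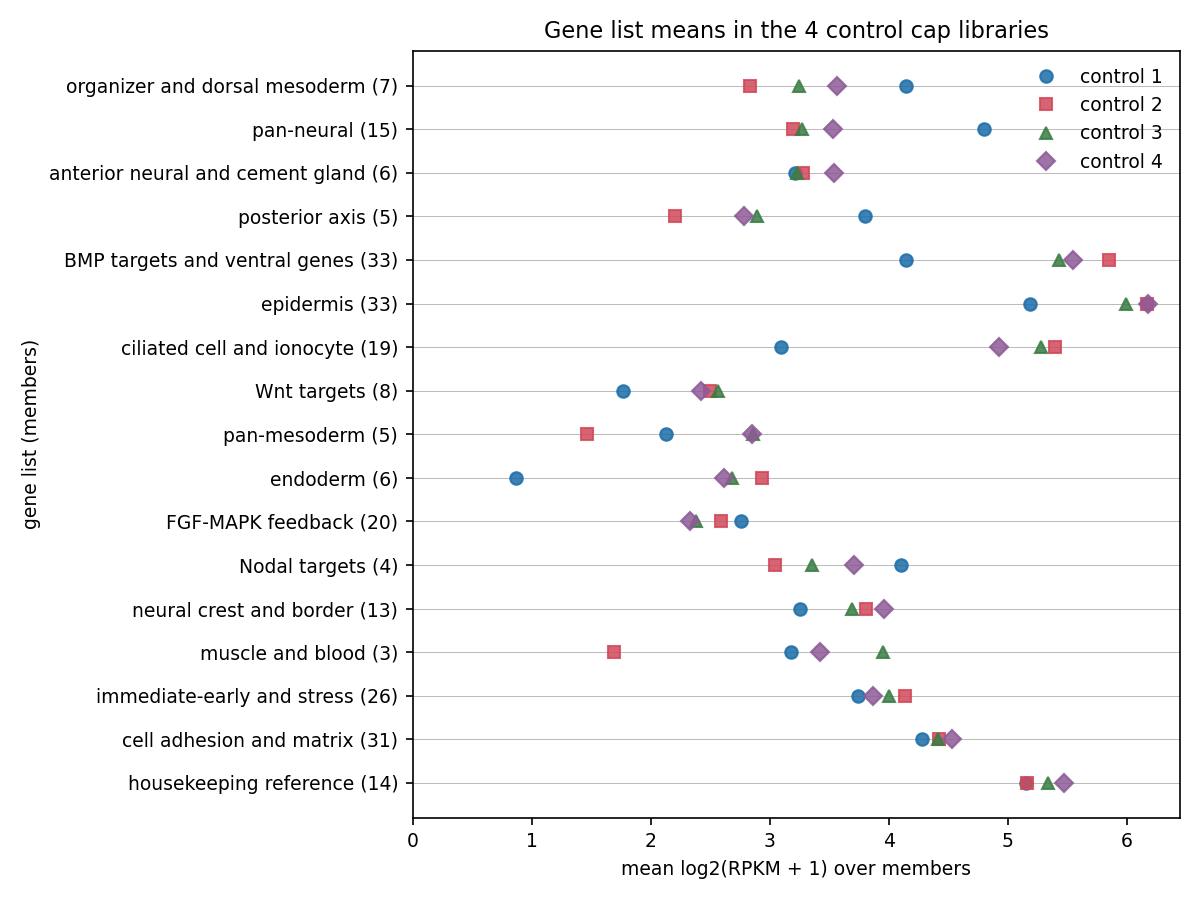
Mean log2(RPKM + 1) of the fixed gene lists in control caps 1 to 4, 1 point per library. Control 1 lies lowest for BMP targets (4.15), epidermis (5.18) and ciliated cells (3.10) and highest for the pan-neural list (4.80).

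Dissociation, which dilutes the signals between cap cells, raised genes of the anterior neural plate and lowered genes of ionocytes and multiciliated cells. HESX1 (Xelaev18001776m), a homeobox gene of the anterior neural plate, rose from 3.22 ± 1.62 RPKM in control caps to 67.9 ± 9.13 in dissociated caps (SD, n = 3 each), a log2 change of 4.09 ± 0.323 (SE, adjusted p = 0.0178). The homeobox gene crx.L, whose human match in the files is OTX2, rose from 25.3 ± 8.39 to 398 ± 54.8 RPKM (adjusted p = 0.0128). The forebrain gene fezf2.S rose by 3.08 ± 0.27 on the log2 scale from 0.0973 RPKM in controls (adjusted p = 0.0178), and six3.S, a gene of the eye field and forebrain, by 3.18 ± 0.411 (adjusted p = 0.0367). In the other direction foxi1.S, the regulator of ionocytes, fell from 104 ± 82.8 to 2.15 ± 1.07 RPKM (log2 change -4.84 ± 0.541, adjusted p = 0.0276). ATP6V1G3 (Xelaev18023455m), a proton pump subunit, fell from 20.3 to 0.557 RPKM (adjusted p = 0.0253), and myb.S, a regulator of multiciliated cells, from 18.0 to 1.19 RPKM (adjusted p = 0.0362).

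By list, 5 of 12 measured transcripts of the anterior neural and cement gland list rose after dissociation and 0 fell, with 11 rising when adjusted over the list alone. Its median log2 change was 2.78 (camera adjusted p = 2.28e-40, and 0.0214 with an estimated correlation). Of 23 pan-neural transcripts 3 rose (17 adjusted over the list alone), with a median of 2.16 (adjusted p = 5.16e-33, but adjusted p = 0.0928 with an estimated correlation). Of 11 organizer and dorsal mesoderm transcripts 3 rose (6 adjusted over the list alone), namely 2 HESX1 models and gsc.L, a homeobox gene of the organizer, at 4.37 ± 1.22 RPKM against 0.0982 in controls. The median of that list was 2.27 (adjusted p = 8.09e-17, and 0.0295 with an estimated correlation). The Nodal target list, which shares gsc.L, had a median of 1.63 with 1 of 6 rising and 3 rising and 1 falling adjusted over the list alone (adjusted p = 5.95e-06, but adjusted p = 0.0597 with an estimated correlation).

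Lists of ventral and epidermal genes were lower after dissociation. None of the 35 BMP target transcripts passed over all genes and 24 fell adjusted over the list alone. Their median was -2.50 (adjusted p = 5.01e-20, but 0.188 with an estimated correlation). The secreted BMP target szl.L stood at 214 ± 171 RPKM in control and 2.60 ± 2.99 in dissociated caps (adjusted p = 0.0666). The BMP pseudoreceptor gene bambi.L stood at 242 ± 114 and 25.4 ± 33.6 (adjusted p = 0.155). Of 33 epidermis transcripts 1 fell, foxi1.S (23 adjusted over the list alone), with a median of -1.78 (adjusted p = 2.67e-17, but adjusted p = 0.0924 with an estimated correlation). Of 20 ciliated cell and ionocyte transcripts 2 fell, foxi1.S and myb.S (14 adjusted over the list alone), with a median of -2.41 (adjusted p = 2.07e-20, but adjusted p = 0.155 with an estimated correlation). In these 3 lists control 1 itself averaged 4.15, 5.18 and 3.10, below the other controls.

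Smaller shifts with no single transcript called were a median of 0.60 for the immediate-early and stress list (adjusted p = 0.00231, but adjusted p = 0.539 with an estimated correlation) and 0.41 for FGF-MAPK feedback (adjusted p = 0.00277, but adjusted p = 0.39 with an estimated correlation). The median was 0.76 for 6 posterior axis transcripts (adjusted p = 0.0482, but adjusted p = 0.354 with an estimated correlation) and -1.56 for 6 endoderm transcripts (adjusted p = 0.023, but adjusted p = 0.39 with an estimated correlation). With L and S copies summed neither of these last 2 lists passed (adjusted p = 0.233 and 0.0871). By control set 1, 2 and 3, the medians were -0.11, 0.90 and 1.18 for the stress list, -0.34, 0.95 and 0.98 for FGF-MAPK feedback and 0.16, 2.17 and 0.06 for posterior axis. For endoderm they were -0.23, -2.13 and -1.80, and control 1 itself averaged 0.86 for this list. The Wnt target, pan-mesoderm, neural crest and muscle lists did not pass (adjusted p = 0.519, 0.209, 0.594 and 0.597). One Wnt target, SALL4 (Xelaev18046188m), a pluripotency and limb patterning factor, rose by 2.39 ± 0.27 (adjusted p = 0.0276).

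Over all 15820 transcripts tested, dissociation raised 23 and lowered 27, and 1519 had an unadjusted p under 0.05. Under median scaling the split was 21 higher to 16 lower. With the control set as a block 239 transcripts were called, 104 higher and 135 lower, including the 50. With the block, 13 pan-neural, 8 anterior neural, 5 organizer and 3 Nodal target transcripts rose, and 8 BMP target, 3 epidermis and 3 ciliated cell transcripts fell. In that fit 2 Wnt target transcripts rose and 1 fell, 2 neural crest transcripts rose and 2 fell, and 1 muscle and 1 stress transcript fell. The count moved with each of the 6 libraries left out. It was 375 without control 1, 1 without control 2 and 0 without control 3 (966 at an unadjusted p under 0.05 by limma). It was 1 without dissociated 1, 0 without dissociated 2 (985 at an unadjusted p under 0.05 by limma) and 99 without dissociated 3. On recovered reads voom called 4, and 511 with the block. Without a filter on low values limma called 0 (2599 at an unadjusted p under 0.05), and with a pseudocount of 5 it called 22.

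**Figure D2:**
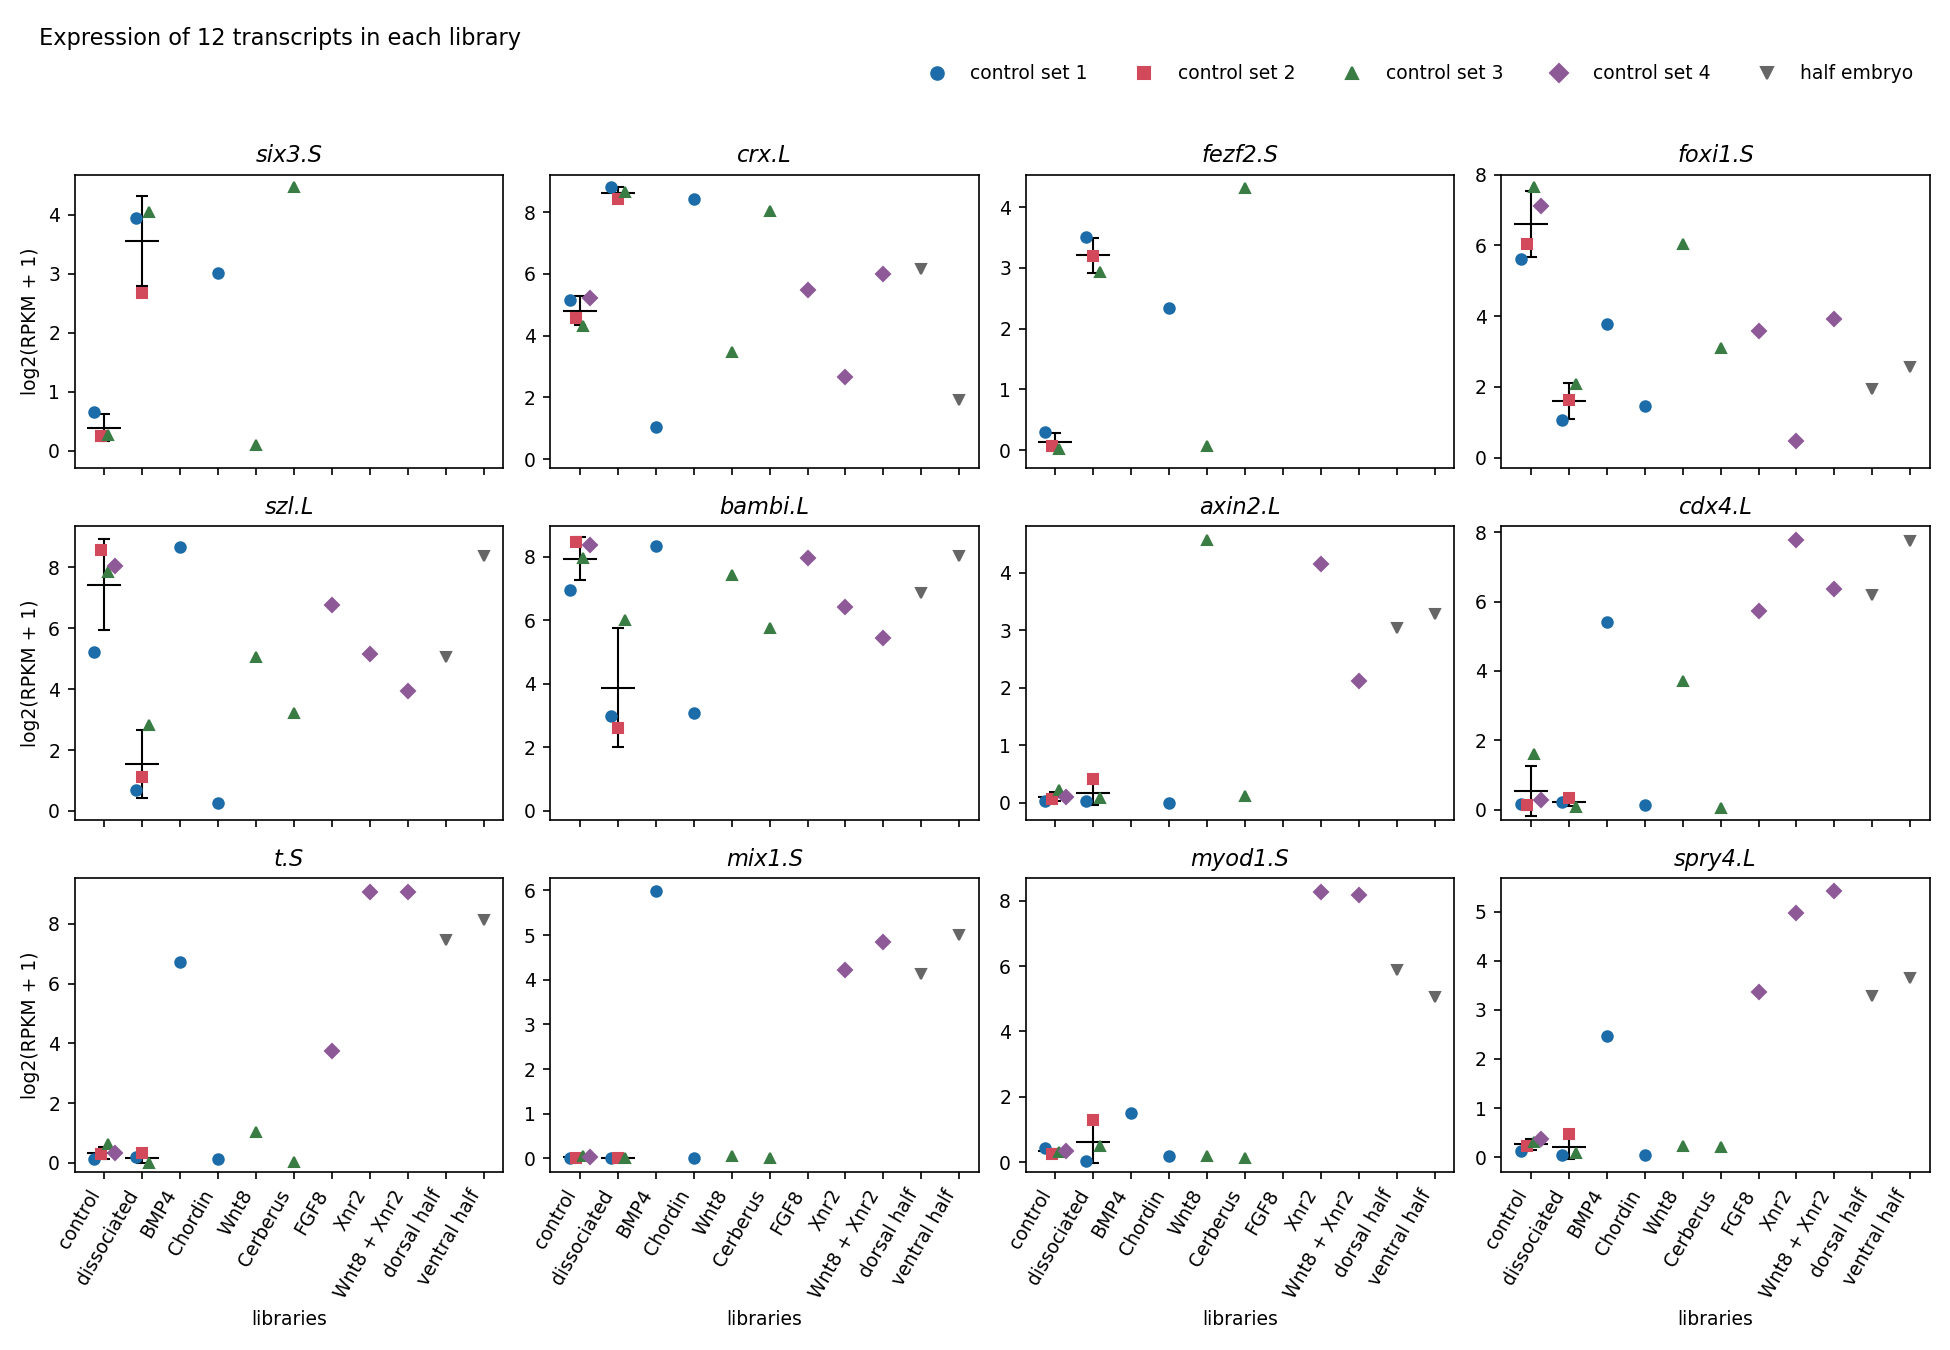
Expression of 12 transcripts, as log2(RPKM + 1), in each library that lists them, by control set, with black bars for the mean and SD of the control and dissociated libraries; a missing marker means that no value is listed. The transcript crx.L rises from a mean of 25.3 RPKM in controls 1 to 3 to 398 after dissociation, and t.S reaches 538 RPKM after Xnr2.

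BMP4, the ventralising ligand, turned on genes of ventral and posterior mesoderm. TBX6 (Xelaev18010507m), a T-box gene of presomitic mesoderm, rose from 1.495 ± 1.481 RPKM in control caps (SD, n = 4) to 251 (log2 change 6.82 ± 0.583 SE, adjusted p = 0.00085). Brachyury, the pan-mesodermal t.S, rose from 0.277 to 104 RPKM (6.37 ± 0.297, adjusted p = 3.11e-05). The mesendodermal homeobox gene mix1.S rose from 0.0193 to 62.0 RPKM (5.95 ± 0.228, adjusted p = 1.82e-05). The Wnt ligand gene of the ventrolateral mesoderm, wnt8a.L, rose from 0.245 to 58.5 (5.59 ± 0.328, adjusted p = 0.000105). The posterior homeobox genes cdx2.L and cdx4.L rose by 5.16 and 4.87. Both copies of crx fell: crx.L from 28.1 ± 8.85 to 1.05 RPKM (-3.78 ± 0.393, adjusted p = 0.00272) and crx.S from 21.1 to 0.494 RPKM (-3.77, adjusted p = 0.0263).

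In the pan-mesoderm list 16 of 19 measured transcripts rose after BMP4 and 0 fell (18 adjusted over the list alone), with a median of 4.47 (adjusted p = 0.0164 with an estimated correlation). Of 20 Nodal target transcripts 15 rose (16 up and 2 down adjusted over the list alone), including eomes.L by 4.47 (median 3.06, adjusted p = 3.1e-218, and adjusted p = 0.0164 with an estimated correlation). In the endoderm list 6 of 9 rose over all genes and adjusted over the list alone, including sox17a.S from 0.775 to 18.7 RPKM (median 2.65, adjusted p = 2.17e-98, and adjusted p = 0.0164 with an estimated correlation). Of 16 posterior axis transcripts 11 rose (12 adjusted over the list alone; median 2.13, adjusted p = 1.46e-71, and adjusted p = 0.0192 with an estimated correlation). Of 22 Wnt targets 11 rose (13 adjusted over the list alone; median 1.78, adjusted p = 2.05e-86, and adjusted p = 0.0254 with an estimated correlation). Of 28 FGF-MAPK feedback transcripts 5 rose (15 adjusted over the list alone), including the FGF antagonist spry4.L by 2.22 and the ligand fgf8.S by 3.56 (median 2.05, adjusted p = 1.24e-55, and adjusted p = 0.0316 with an estimated correlation). Several of these lists share t.S, mix1.S and cdx genes. The 4 muscle and blood transcripts had a median of 1.55 (0 called over all genes, 2 rising adjusted over the list alone; adjusted p = 0.0341, but adjusted p = 0.161 with an estimated correlation and adjusted p = 0.128 with L and S copies summed).

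The 5 anterior neural transcripts had a median of -2.95, with 0 called over all genes and 4 falling adjusted over the list alone (adjusted p = 9.66e-10, and adjusted p = 0.0179 with an estimated correlation). Their median against control 1 was -4.43. BMP targets and ventral genes did not pass against the 4 controls: 0 of 32 changed over all genes, 1 rose adjusted over the list alone, and the median was 0.18 (adjusted p = 0.749). Against the matched control 1, in which this list was low, the median log2 ratio was 1.46, and with the control set as a block the adjusted p was 6.35e-09 (median 1.16, test upward). The transcript szl.L read 408 RPKM after BMP4, 36.7 in control 1 and 227 ± 142 over the 4 controls. The ciliated cell list had a median of -1.14 against the 4 controls (16 transcripts, 0 called in either count; adjusted p = 2.39e-06, but adjusted p = 0.194 with an estimated correlation) and of 0.72 against control 1, whose mean for this list was 3.10, and -0.23 with the block. The epidermis list had a median of -0.27 (30 transcripts, 0 called in either count; adjusted p = 0.000148, but adjusted p = 0.272 with an estimated correlation, and adjusted p = 0.0881, median -0.07, with the block). With the block, the organizer, pan-neural, neural crest and stress lists passed (adjusted p = 0.0358, 6.8e-05, 2.99e-05 and 4.07e-09), which without it did not (adjusted p = 0.146, 0.603, 0.466 and 0.348). With it the pan-neural list tested downward, with a median of -0.43 against 0.12 without it, and the other 3 upward, with medians of 0.80, 0.36 and 0.91.

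In all, 67 of 16049 transcripts rose after BMP4 and 2 fell, each in the same direction against control 1, and 419 had an unadjusted p under 0.05. With the control set as a block 44 were called (40 higher, 4 lower, 38 of them shared), with 7 Wnt target, 5 posterior axis, 12 pan-mesoderm, 3 endoderm, 3 FGF-MAPK feedback and 8 Nodal target transcripts rising and 1 anterior neural transcript falling. Without control 1, 116 were called, and with a pseudocount of 0.1, 16. On recovered reads voom called 29, and 0 with the block (485 at an unadjusted p under 0.05), so that all 12 transcripts of the rule for named genes lost their call in that fit. The median change of all transcripts was 0.16, and 0.04 after quantile normalization.

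Chordin, which binds BMPs outside the cell, gave changes in the direction of dissociation, most of them short of the threshold for 1 library. The crx.L transcript rose from 28.1 ± 8.85 RPKM in control caps (SD, n = 4) to 347 (3.63 ± 0.385 SE, adjusted p = 0.046), with 34.8 in the matched control. The head homeobox gene otx1.L read 291 RPKM against 21.9 ± 23.9 (adjusted p = 0.721). The BMP target szl.L read 0.192 RPKM against 227 ± 142 (log2 change -7.17 ± 1.16, adjusted p = 0.217) and 36.7 in the matched control. In the same library bambi.L read 7.35 against 265 ± 104 (adjusted p = 0.639). The ionocyte regulator foxi1.S read 1.74 RPKM against 112 ± 69.6 (adjusted p = 0.173).

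As groups, 8 of 9 anterior neural transcripts rose adjusted over the list alone and 0 over all genes, with a median of 2.84 (adjusted p = 4.44e-37). The repeat with an estimated correlation (adjusted p = 0.0179) covered 4 of these 9 transcripts, those with a value in every library. Of 22 pan-neural transcripts 15 rose adjusted over the list alone and 0 over all genes (median 2.38, adjusted p = 9.41e-45, but adjusted p = 0.0586 with an estimated correlation). Of 9 organizer transcripts 6 rose and 1 fell adjusted over the list alone, 0 over all genes (median 2.63, and 1.57 against control 1; adjusted p = 1.21e-10, and adjusted p = 0.0486 with an estimated correlation). Of 30 BMP target transcripts 23 fell adjusted over the list alone and 0 over all genes (median -2.90, adjusted p = 5.82e-47, but adjusted p = 0.0606 with an estimated correlation). Against control 1, itself low for this list at 4.15, the median was -2.38. The ciliated cell list, with 10 of 16 falling adjusted over the list alone and 0 over all genes, had a median of -2.45 (adjusted p = 3.44e-26, but adjusted p = 0.0582 with an estimated correlation) and of -1.06 against control 1. The epidermis list had a median of -1.44, with 1 of 30 falling adjusted over the list alone and 0 over all genes (adjusted p = 3.69e-14, but adjusted p = 0.0928 with an estimated correlation), and -0.70 against control 1.

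After Chordin the posterior axis list had a median of 0.58 over 5 transcripts (1 rising adjusted over the list alone, 0 over all genes; adjusted p = 0.00515, but adjusted p = 0.213 with an estimated correlation and adjusted p = 0.0871 with L and S copies summed). The stress list had a median of -0.47 over 23 (0 called in either count; adjusted p = 0.00469, but adjusted p = 0.506 with an estimated correlation, and adjusted p = 0.551, median -0.11, test upward, with the control set as a block). The Wnt target, pan-mesoderm and Nodal target lists did not pass (adjusted p = 0.157, 0.485 and 0.302) but did with the block (adjusted p = 0.017, 0.0113 and 0.0373), each tested upward. The Nodal target median was nonetheless -0.37 with the block, -0.36 without it and -1.12 against control 1, and the Wnt target median was 0.07, 0.28 and -0.15. The endoderm, FGF-MAPK, neural crest and muscle lists did not pass either way (adjusted p = 0.0637, 0.285, 0.209 and 0.474 without the block).

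Of 15583 transcripts, 2 were called after Chordin, both higher: crx.L and the injected CHRD (Xelaev18029538m). In the same limma fit 167 were higher and 292 lower at an unadjusted p under 0.05, and voom on recovered reads called 2. With the block 1 was called, the injected CHRD, and crx.L was not (adjusted p = 0.0943). Without control 1 there were 76 (30 higher, 46 lower), and without control 2, 3 or 4 there was 1 each, with crx.L not called (adjusted p = 0.141, 0.0675 and 0.0757). Nor was crx.L called with a pseudocount of 0.1 (adjusted p = 0.0599) or without a filter on low values (adjusted p = 0.451), and voom with the block left 1 call.

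Wnt8, a ligand of the canonical Wnt pathway, raised its feedback target axin2.L from 0.0792 RPKM in control caps (n = 4) to 22.8 (4.46 ± 0.264 SE, adjusted p = 0.000822). The receptor gene ror2.S rose from 0.766 ± 0.15 to 22.8 RPKM (3.76 ± 0.456, adjusted p = 0.0339). The Hox gene hoxd1.S rose by 3.36 ± 0.384 (adjusted p = 0.033). PAX3 (Xelaev18027783m), a gene of the neural border, rose by 3.27 ± 0.388 (adjusted p = 0.033), and the posterior mesoderm gene evx1.L by 2.59 (adjusted p = 0.033). The Wnt-induced transcription factor sp5.S rose by 2.02 (adjusted p = 0.0251). Its homeolog sp5.L read 13.1 RPKM against 0.73 ± 0.416 (adjusted p = 0.0558).

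In the Wnt target list 6 of 25 transcripts rose after Wnt8 and 0 fell (14 adjusted over the list alone; median 1.44, adjusted p = 7.33e-107, and adjusted p = 0.0179 with an estimated correlation). Of 14 posterior axis transcripts 4 rose (8 adjusted over the list alone; median 1.72, adjusted p = 3.22e-50, and adjusted p = 0.031 with an estimated correlation). The pan-mesoderm list had 3 of 9 rising adjusted over the list alone and 0 over all genes (median 1.43, and 0.84 against the matched control 3 and 0.94 with the block; adjusted p = 6.68e-17, and adjusted p = 0.0349 with an estimated correlation). In the neural crest and border list 1 of 16 rose, PAX3 (2 adjusted over the list alone; median 0.76, adjusted p = 6.33e-06, but adjusted p = 0.173 with an estimated correlation). With the control set as a block the median of this list turned to -0.07 and 0 members rose (adjusted p = 2.59e-05, test upward). The pan-neural list had a median of 0.56 with 2 of 24 rising adjusted over the list alone and 0 over all genes (adjusted p = 2.03e-06, but adjusted p = 0.316 with an estimated correlation; median 0.95 with the block). The anterior neural list was lower, with a median of -0.79 over 7 transcripts (adjusted p = 0.000477, and 0.0291 with an estimated correlation). So was the organizer list, at -0.68 over 7 (adjusted p = 0.000256, but 0.0597 with an estimated correlation). In these lower lists, and in the next 4, no transcript was called in either count.

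BMP targets had a median of -0.54 after Wnt8 (adjusted p = 0.00509, but adjusted p = 0.545 with an estimated correlation) and epidermis -0.42 (adjusted p = 0.000684, but adjusted p = 0.367 with an estimated correlation). Ciliated cells had a median of -0.54 (adjusted p = 0.00167, but adjusted p = 0.455 with an estimated correlation) and the stress list -0.27 (adjusted p = 0.0351, but adjusted p = 0.683 with an estimated correlation and adjusted p = 0.0795 with L and S copies summed). With the control set as a block the medians of these 4 lists were -1.37, -0.68, -1.10 and -0.52. The endoderm list passed with the block (adjusted p = 0.0156, median -0.96, test downward) and not without it (adjusted p = 0.427). The FGF-MAPK, Nodal and muscle lists did not pass (adjusted p = 0.834, 0.574 and 0.91). Over 15824 transcripts 12 rose, the injected wnt8a.L among them, and 0 fell. At an unadjusted p under 0.05 limma had 185 higher and 138 lower, and voom on recovered reads called 0. With the block limma called 0 (474 at an unadjusted p under 0.05), so none of the list members above rose in that fit. Without control 1, 2 or 4 the counts were 29, 2 and 1. They were 0 with a pseudocount of 0.1 (280 at an unadjusted p under 0.05 by limma), 30 with a pseudocount of 5, 2 with summed copies and 3 with voom and the block.

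Cerberus, a secreted protein that binds Nodal, BMP and Wnt ligands, raised anterior neural genes. The transcript fezf2.S rose from 0.0973 ± 0.118 RPKM in the controls that list it (SD, n = 3) to 19.0 (4.19 ± 0.38 SE, adjusted p = 0.0176). HESX1 (Xelaev18001776m) rose from 3.20 to 63.4 RPKM (3.99 ± 0.413, adjusted p = 0.0176). PKDCC (Xelaev18026172m), which encodes a secreted kinase, rose by 4.25 ± 0.428 (adjusted p = 0.0176). The retinol acyltransferase gene lrat.L rose from 0.7231 to 30.02 RPKM (adjusted p = 0.0111). The single transcript called lower was BMP7 (Xelaev18018155m), a BMP ligand, which fell from 357 ± 112 to 39.8 RPKM (-3.07 ± 0.389, adjusted p = 0.0419).

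Of 13 anterior neural transcripts 2 rose after Cerberus (11 adjusted over the list alone; median 3.15, adjusted p = 2.89e-64). The repeat with an estimated correlation (adjusted p = 0.0179) covered 6 of these 13 transcripts. Of 23 pan-neural transcripts 2 rose (15 adjusted over the list alone; median 2.36, adjusted p = 3.66e-38, but adjusted p = 0.0597 with an estimated correlation). Of 11 organizer transcripts 1 rose, HESX1 (8 up and 2 down adjusted over the list alone; median 2.49, adjusted p = 2.24e-16, and adjusted p = 0.031 with an estimated correlation). BMP targets had a median of -2.12, with 5 of 34 falling adjusted over the list alone and 0 over all genes (adjusted p = 3.49e-27, but adjusted p = 0.0925 with an estimated correlation). Ciliated cell genes had a median of -1.69, with 3 of 20 falling adjusted over the list alone and 0 over all genes (adjusted p = 9.83e-18, but adjusted p = 0.084 with an estimated correlation). For epidermis the median was -1.33, with 1 of 30 falling adjusted over the list alone and 0 over all genes (adjusted p = 1.1e-12, but adjusted p = 0.1 with an estimated correlation). Endoderm stood at -1.61 with 0 of 6 called in either count (adjusted p = 0.00274, but adjusted p = 0.188 with an estimated correlation), and control 1, 1 of the 4 controls, averaged 0.86 for this list. The endoderm median was -1.99 against the matched control 3. Nodal targets stood at 1.35, with 3 of 6 rising and 1 falling adjusted over the list alone and 0 over all genes (adjusted p = 0.000137, but adjusted p = 0.0733 with an estimated correlation).

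The stress list had a median of -0.17 after Cerberus with 0 of 29 called in either count (adjusted p = 0.00135, but adjusted p = 0.427 with an estimated correlation; median -0.64 with the control set as a block). The posterior axis, Wnt target, pan-mesoderm, FGF-MAPK, neural crest and muscle lists did not pass (adjusted p = 0.947, 0.392, 0.963, 0.33, 0.702 and 0.963). Of 15942 transcripts 11 rose, including the injected cer1.S, and 1 fell, with 549 at an unadjusted p under 0.05. With the block 6 were called, all higher and 4 of them shared, and of the list members 1 anterior neural transcript rose. In that fit fezf2.S kept its call (adjusted p = 0.0396), while BMP7, HESX1, PKDCC and lrat.L lost theirs (adjusted p = 0.098, 0.0971, 0.0764 and 0.0536). Without control 1 there were 87 (27 higher, 60 lower), and without control 2, 3 or 4 there were 3, 1 and 3. On recovered reads voom called 4, and 34 with the block. Without a filter on low values 1 was called, with a pseudocount of 0.1 there were 5, and with median scaling 6.

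FGF8, a fibroblast growth factor, raised posterior and mesodermal genes. The posterior homeobox gene cdx4.L rose from 0.622 ± 0.966 RPKM in controls (SD, n = 4) to 51.8 (5.18 ± 0.543 SE, adjusted p = 0.0116), and wnt8a.L to 37.0 RPKM (4.94 ± 0.339, adjusted p = 0.00141). The T-box gene t.S rose from 0.277 to 12.4 RPKM (3.41 ± 0.296, adjusted p = 0.00501), pnhd.L from 1.12 to 56.3 RPKM (adjusted p = 0.0428) and hoxd1.S by 3.59 (adjusted p = 0.0132). Among genes of FGF feedback, spry4.L rose by 3.10 ± 0.28 to 9.29 RPKM (adjusted p = 0.00561), while spry2.S read 21.0 RPKM against 1.20 ± 0.894 (adjusted p = 0.171).

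In the Wnt target list 9 of 18 transcripts rose after FGF8 and 0 fell (13 adjusted over the list alone; median 2.49, adjusted p = 2.87e-77, and adjusted p = 0.0214 with an estimated correlation). Those that rose include cdx4.L, hoxd1.S and t.S, which are also posterior or mesodermal genes. In the posterior axis list 7 of 14 rose (9 adjusted over the list alone; median 2.21, adjusted p = 2.18e-52, and adjusted p = 0.031 with an estimated correlation). In the pan-mesoderm list 6 of 11 rose in either count, with a median of 2.60. Its camera adjusted p was 5.19e-54, and 0.031 with an estimated correlation. Of 23 FGF-MAPK feedback transcripts 2 rose (14 adjusted over the list alone; median 1.84, adjusted p = 9.81e-42, and adjusted p = 0.031 with an estimated correlation). Of 7 Nodal targets 2 rose (3 adjusted over the list alone; median 1.22, adjusted p = 8.24e-14, and adjusted p = 0.0291 with an estimated correlation). Of 20 pan-neural transcripts 2 rose (5 adjusted over the list alone; median 0.93, adjusted p = 1.15e-15, but adjusted p = 0.155 with an estimated correlation). The ciliated cell list was lower, with a median of -1.88, 2 of 18 falling adjusted over the list alone and 0 over all genes (adjusted p = 4.77e-11, but adjusted p = 0.161 with an estimated correlation). The neural crest list had a median of 0.96 with 0 of 16 called in either count (adjusted p = 0.000413, but adjusted p = 0.106 with an estimated correlation). The organizer list stood at 0.55 (0.33 with the control set as a block), with 2 of 8 rising adjusted over the list alone and 0 over all genes (adjusted p = 0.00749, but adjusted p = 0.165 with an estimated correlation).

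The epidermis, endoderm and muscle lists passed after FGF8 with the control set as a block (adjusted p = 0.000146, 0.0334 and 0.0185) and not without it (adjusted p = 0.121, 0.247 and 0.113). With it each tested downward, with medians of -0.46, -1.60 and -1.17. The anterior neural, BMP target and stress lists did not pass (adjusted p = 0.855, 0.754 and 0.574). Of 14316 transcripts 24 rose, the injected fgf8.L among them, and 0 fell. By limma 324 were higher and 189 lower at an unadjusted p under 0.05, and voom on recovered reads called 24. With the block 1 was called, so of the list members above none rose in that fit. Without control 1, 2 or 4 the counts were 40, 8 and 66. They were 1 with a pseudocount of 0.1, 59 with a pseudocount of 5, 10 with summed copies, 37 with quantile normalization, 10 with the names of control set 4 kept, and 0 with voom and the block (463 at an unadjusted p under 0.05).

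Xnr2, a Nodal ligand that induces mesoderm and endoderm, raised genes of mesoderm, muscle and the posterior axis and lowered genes of ionocytes and multiciliated cells. Brachyury (t.S) rose from 0.277 ± 0.19 RPKM in controls (SD, n = 4) to 538 (8.73 ± 0.292 SE, adjusted p = 1.32e-06). The muscle regulator myod1.S rose from 0.262 to 309 (7.94 ± 0.428, adjusted p = 7.95e-06), and its relative myf5.L to 203 RPKM (7.66 ± 0.238, adjusted p = 1.27e-06). The posterior homeobox gene cdx2.S rose from 0.204 to 257 RPKM (adjusted p = 1.96e-06). The ionocyte regulators foxi1.L and foxi1.S fell from 219 ± 116 to 1.14 RPKM (-6.47 ± 0.795, adjusted p = 0.00147) and from 112 ± 69.6 to 0.397 (adjusted p = 0.00121). The neural gene lhx5.L fell from 30.3 ± 16.7 to 1.78 RPKM (adjusted p = 0.0101). The multiciliated cell regulators myb.S and gmnc-like.L fell by 3.82 and 3.72 on the log2 scale (adjusted p = 0.00294 and 0.031).

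In the pan-mesoderm list 28 of 32 transcripts rose after Xnr2 and 0 fell (29 adjusted over the list alone; median 5.21, adjusted p = 4.42e-262, and adjusted p = 0.0164 with an estimated correlation). In the posterior axis list 21 of 25 rose (23 adjusted over the list alone; median 4.05, adjusted p = 1.55e-113, and adjusted p = 0.0179 with an estimated correlation). In the Wnt target list 21 of 27 rose (22 adjusted over the list alone; median 4.04, adjusted p = 2.77e-113, and adjusted p = 0.0214 with an estimated correlation), including axin2.L at 16.7 RPKM. Of 18 Nodal targets 14 rose (15 up and 2 down adjusted over the list alone; median 3.77, adjusted p = 3.21e-72, and adjusted p = 0.0214 with an estimated correlation). Of 11 muscle and blood transcripts 7 rose and 1 fell (9 and 1 adjusted over the list alone; median 3.58, adjusted p = 3.69e-40, and adjusted p = 0.0254 with an estimated correlation). Of 29 FGF-MAPK feedback transcripts 17 rose (23 adjusted over the list alone; median 2.97, adjusted p = 5.41e-42, and adjusted p = 0.031 with an estimated correlation). Of 11 endoderm transcripts 4 rose (5 adjusted over the list alone; median 1.74, adjusted p = 1.6e-10, and adjusted p = 0.0386 with an estimated correlation). Of 22 neural crest transcripts 6 rose (8 adjusted over the list alone; median 1.18, adjusted p = 0.000317, and adjusted p = 0.0349 with an estimated correlation). Of 15 organizer transcripts 8 rose (10 up and 3 down adjusted over the list alone; median 2.34, adjusted p = 5.27e-15, but adjusted p = 0.106 with an estimated correlation).

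Of 22 pan-neural transcripts 8 rose after Xnr2, among them the homeobox gene irx3.L by 2.81, and 1 fell, lhx5.L (8 and 3 adjusted over the list alone; median 0.93, adjusted p = 0.0248, but adjusted p = 0.545 with an estimated correlation). The anterior neural list had a median of -2.85, with 4 of 6 falling adjusted over the list alone and 0 over all genes (adjusted p = 0.00926, and adjusted p = 0.0453 with an estimated correlation). Ciliated cell genes had a median of -2.32, with 4 of 19 falling (9 adjusted over the list alone; adjusted p = 2.97e-05, but adjusted p = 0.253 with an estimated correlation). For epidermis the median was -1.55, with 4 of 33 falling and 1 rising in either count. Its camera adjusted p was 0.00157, but 0.28 with an estimated correlation. BMP targets had a median of -1.31 with 1 of 33 rising, msx2.S, over all genes and adjusted over the list alone (adjusted p = 0.0712), and passed with the control set as a block (adjusted p = 0.00912, median -1.60, test downward), where no member rose and msx2.S lost its call. The stress list did not pass (adjusted p = 0.271). Of 14770 transcripts 545 rose and 66 fell, and 2181 had an unadjusted p under 0.05. On recovered reads voom with the block called 353. With the block 5 pan-neural and 3 neural crest transcripts rose. In that fit 1 anterior neural and 1 BMP target transcript fell, and no pan-neural or muscle transcript fell. The median change of all transcripts was -0.14 as tested and 0.00 after median scaling.

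**Figure D3:**
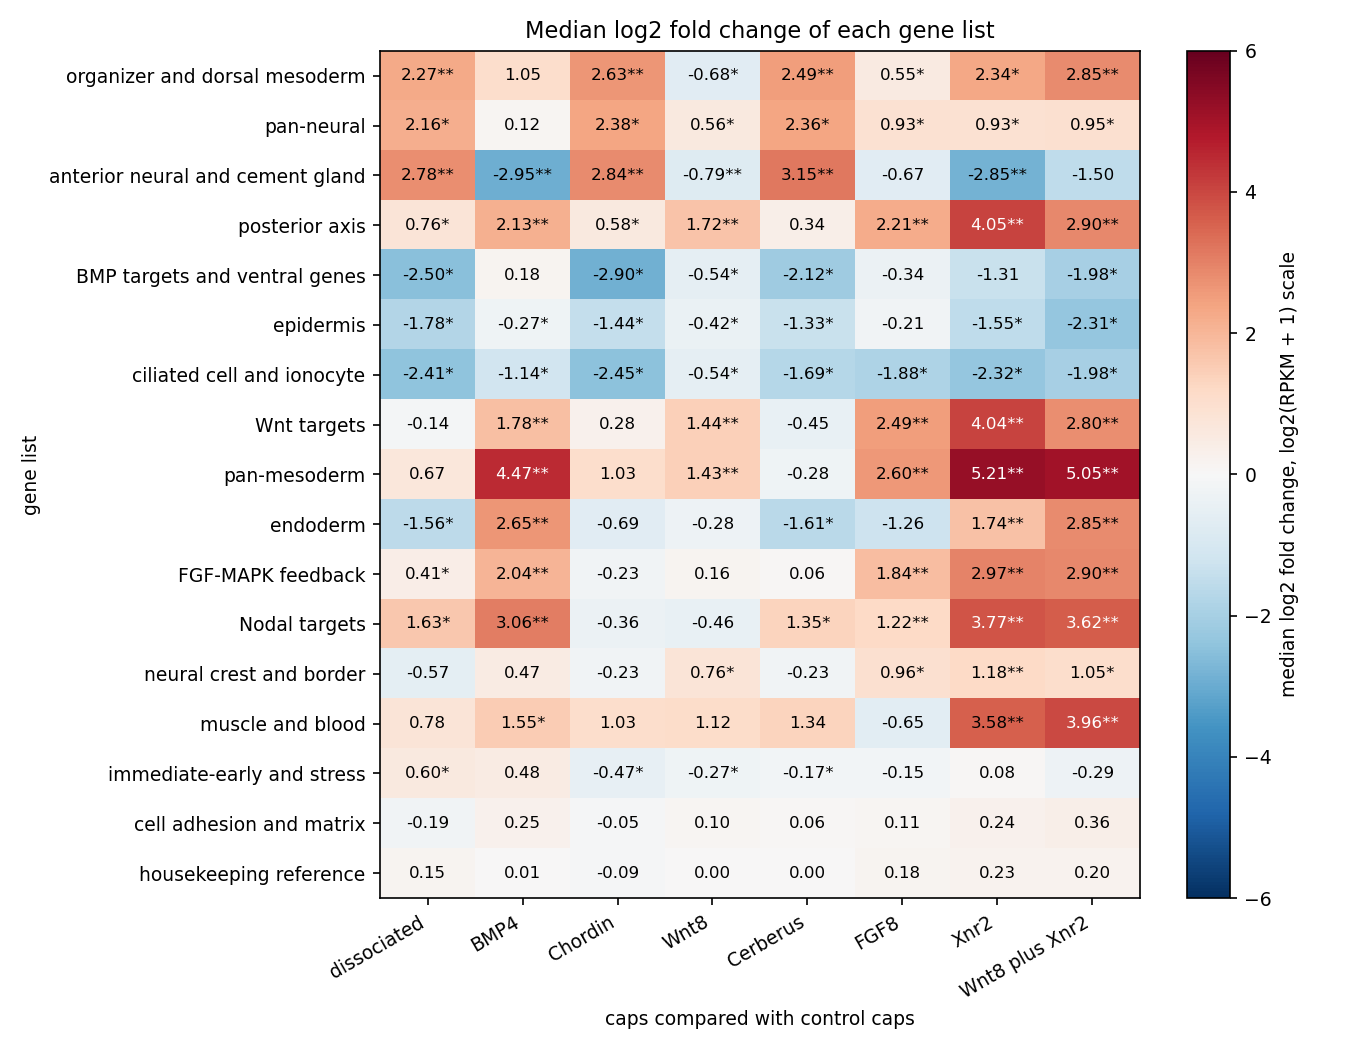
Median log2 change of each fixed gene list (vertical) in each comparison with control caps (horizontal). One asterisk marks an adjusted p under 0.05 with the preset correlation, a pair of asterisks a call that holds with an estimated correlation as well; the pan-mesoderm list reaches 5.21 after Xnr2 and the anterior neural list 3.15 after Cerberus.

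Wnt8 together with Xnr2 raised t.S to 534 RPKM (8.72 ± 0.293 SE, n = 4 controls, adjusted p = 1.38e-06) and myod1.S to 288 RPKM (7.84 ± 0.428, adjusted p = 7.95e-06). The axial mesoderm gene foxa4.L rose from 0.0617 to 346 RPKM (8.35 ± 0.831, adjusted p = 0.000382). The gene of Cerberus, cer1.S, rose from 0.109 to 102 RPKM (6.54 ± 0.474, adjusted p = 4.74e-05), and the endoderm gene sox17a.S from 0.775 to 44.7 RPKM (4.74 ± 0.432, adjusted p = 0.000212). The organizer homeobox gene lhx1.L rose to 53.1 RPKM (5.59 ± 0.222). Among those that fell were the neural gene lhx5.L (-3.26 ± 0.566, adjusted p = 0.0129), myb.S (-3.07 ± 0.523, adjusted p = 0.0115), the FGF receptor gene fgfr4.S (89.8 ± 11.4 to 15.2 RPKM, adjusted p = 0.00094) and the Wnt receptor gene fzd8.S (-2.47 ± 0.349, adjusted p = 0.00359).

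In the pan-mesoderm list 25 of 28 transcripts rose after the double injection (26 adjusted over the list alone; median 5.05, adjusted p = 2.2e-256, and adjusted p = 0.0164 with an estimated correlation). Of 28 Nodal targets 23 rose (24 up and 1 down adjusted over the list alone; median 3.62, adjusted p = 1.49e-133, and adjusted p = 0.0164 with an estimated correlation). Of 21 organizer transcripts 13 rose (15 up and 2 down adjusted over the list alone; median 2.85, adjusted p = 6.12e-59, and adjusted p = 0.0294 with an estimated correlation). Of 15 endoderm transcripts 9 rose (10 adjusted over the list alone; median 2.85, adjusted p = 6.93e-41, and adjusted p = 0.0164 with an estimated correlation). Of 22 posterior axis transcripts 18 rose (20 adjusted over the list alone; median 2.90, adjusted p = 7.75e-69, and adjusted p = 0.0192 with an estimated correlation). Of 25 Wnt targets 19 rose (21 adjusted over the list alone; median 2.80, adjusted p = 2.4e-73, and adjusted p = 0.0214 with an estimated correlation). Of 28 FGF-MAPK feedback transcripts 15 rose (21 adjusted over the list alone; median 2.90, adjusted p = 5.31e-41, and adjusted p = 0.0312 with an estimated correlation). Of 12 muscle and blood transcripts 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 3.96, adjusted p = 1.18e-51, and adjusted p = 0.0179 with an estimated correlation). Of 20 neural crest transcripts 6 rose in either count, with a median of 1.05. Their camera adjusted p was 4.31e-05, but 0.0691 with an estimated correlation.

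Of 20 pan-neural transcripts 7 rose after the double injection and 1 fell (7 and 2 adjusted over the list alone; median 0.95, adjusted p = 0.00611, but adjusted p = 0.492 with an estimated correlation). Epidermis had a median of -2.31 with 1 of 33 rising and 0 falling (1 and 4 adjusted over the list alone; adjusted p = 0.000546, but adjusted p = 0.165 with an estimated correlation). Ciliated cell genes had a median of -1.98 with 1 of 19 falling (3 adjusted over the list alone; adjusted p = 0.00364, but adjusted p = 0.318 with an estimated correlation). BMP targets had a median of -1.98 with 0 of 33 called in either count (adjusted p = 0.00038, but 0.307 with an estimated correlation). The anterior neural and stress lists did not pass (adjusted p = 0.508 and 0.855). Of 14989 transcripts 525 rose and 36 fell, and 1641 had an unadjusted p under 0.05. On recovered reads voom with the block called 368. With the control set as a block 4 pan-neural and 4 neural crest transcripts rose, and 1 BMP target, 2 epidermis and 2 ciliated cell transcripts fell. In that fit lhx5.L and myb.S lost their calls (adjusted p = 0.0673 and 0.0704), and 0 pan-neural, 0 muscle and 0 adhesion transcripts fell and 0 stress transcripts rose, against 1, 1, 1 and 2 without it.

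The cell adhesion and matrix list and the housekeeping list passed in none of the 8 comparisons. Their lowest adjusted p, both after FGF8, were 0.121 and 0.103. Their medians lay between -0.19 and 0.36 for adhesion and between -0.09 and 0.23 for housekeeping genes. The housekeeping medians of 0.01 after BMP4, 0.00 after Wnt8 and 0.00 after Cerberus turned to -0.09, -0.03 and -0.04 with median scaling. The FGF-MAPK median of 0.06 after Cerberus turned to -0.01 with quantile normalization. Lists whose median, mean and test pointed in different directions, such as Wnt targets after dissociation (median -0.14, test upward) and BMP targets after BMP4 (median 0.18, test downward), were not called without the block.

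The Wnt8 plus Xnr2 library had higher values of organizer and endoderm genes, and lower values of Wnt targets, than that of Xnr2 alone. With 1 library each, the intervals cover counting error only, so no difference can be assigned to the added Wnt8. Over 15380 transcripts 22 were at least 4-fold higher with both mRNAs and 14 lower. The transcript cer1.S read 102 RPKM with both and 10.4 with Xnr2 alone (9.77-fold, 95% interval 8.90 to 10.8). The endoderm gene sox17a.S read 44.7 and 4.72 (9.47-fold, 8.26 to 10.9), and frzb.L, the gene of a secreted Wnt inhibitor, 23.8 and 2.38 (10.02-fold, 8.24 to 12.3). The transcript crx.L read 63.6 and 5.37 RPKM (11.8-fold, 10.6 to 13.2), and foxi1.L 23.7 and 1.14 (20.7-fold, 16.0 to 27.2). Lower with both were the Wnt target sp5.L, at 3.34 against 26.9 RPKM (0.124-fold, 0.109 to 0.141), and axin2.L at 3.33 against 16.7. So were GBX2 (Xelaev18044833m), a posterior neural gene, at 1.98 against 15.5, msx1.L, a BMP target, at 10.916 against 59.997, and the immediate-early gene junb.L at 5.997 against 49.94. The organizer list had a median log2 ratio of 1.15 over 19 transcripts, Nodal targets 0.95 over 24, ciliated cells 0.68 over 21 and endoderm 0.67 over 13, each at percentile 100 of 10000 matched random lists. Wnt targets had a median of -1.22 over 26, posterior axis -1.07 over 25, BMP targets -0.64 over 45 and the stress list -0.34 over 29, each at percentile 0. Pan-mesoderm lay at -0.01 (percentile 47.0).

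Less far apart in these 2 libraries were the pan-neural list at 0.21 (percentile 99.3), anterior neural at 0.39 (91.4), muscle and blood at 0.34 (99.7) and neural crest at -0.17 (0.37). Others were FGF-MAPK at -0.19 (0.1), epidermis at -0.20 (0.01), cell adhesion at 0.09 (90.6) and housekeeping at 0.05 (68.4). With a 2-fold size rule 450 transcripts differed, and with an 8-fold rule 7.

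The dorsal part, which holds the organizer, was compared with the ventral part in the same way, 1 library each. The BMP antagonist gene CHRD (Xelaev18027420m) read 114 RPKM dorsally and 2.53 ventrally (45.2-fold, 95% interval 39.6 to 51.8). SFRP5 (Xelaev18024021m), the gene of a secreted Wnt inhibitor, read 22.8 and 0.0554, with 4 reads in the ventral library (411-fold, 160 to 1512). The organizer ligand admp.L read 28.5 and 0.736 RPKM (38.7-fold, 28.5 to 53.9) and crx.L 70.0 and 2.79 (25.1-fold, 21.5 to 29.6). Ventrally higher were szl.L, at 32.0 dorsally and 328 ventrally (0.0975-fold, 0.0905 to 0.105), the epidermal regulator tp63.S at 0.116 and 9.19 (0.0126-fold, 0.0073 to 0.0202), and the keratin krt.L at 35.1 and 279 RPKM (0.126-fold, 0.119 to 0.133). Over 14997 transcripts 66 were at least 4-fold higher dorsally and 40 ventrally. With a 2-fold rule 437 differed and with an 8-fold rule 26.

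Of 29 organizer transcripts in these libraries 24 were over 2-fold and 14 over 4-fold higher dorsally (median log2 ratio 2.05). Medians were 1.26 for pan-neural, 1.16 for muscle and blood, 0.64 for anterior neural, 0.41 for Nodal targets and 0.16 for FGF-MAPK. Each ranked at percentile 100 of matched random lists, which is no p-value. At percentile 0 were BMP targets (-1.06), posterior axis (-0.86), Wnt targets (-0.73), ciliated cells (-0.72) and epidermis (-0.61). Others were pan-mesoderm at -0.09 (percentile 0.54), endoderm at -0.04 (14.4), neural crest at 0.06 (94.1), the stress list at 0.08 (99.0), cell adhesion at -0.01 (44.6) and housekeeping at 0.01 (59.7).

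Responses were then compared across transcripts, which are not independent replicates, so no p-value is given. The 95% intervals take them as independent, so they are too narrow and cover no variation between libraries. Dissociation ratios are means over the control sets that the other treatment does not use, 2 for BMP4, Chordin, Wnt8 and Cerberus and 3 for the rest. Of transcripts at least 2-fold changed both by dissociation and by Cerberus, 185 were higher in both and 415 lower in both, where independent lists give 7.06 and 29.8, and 7 went opposite ways. That is 98.9% the same way (exact 95% interval 97.6 to 99.5), with Pearson r = 0.704 and Spearman rho = 0.413 over 15216 transcripts. For dissociation and Chordin 107 were higher and 133 lower in both (5.71 and 10.8 from independent lists) and 17 opposite, 93.4% the same way (89.6 to 96.1; r = 0.448, rho = 0.315 over 14744). Chordin and Cerberus went the same way in 97.9% (95.1 to 99.3), with 96 higher and 132 lower in both (2.32 and 6.06 from independent lists), but rho was 0.0589 beside r = 0.436. For dissociation and Wnt8 the share was 92.9% (89.7 to 95.3; 76 higher and 263 lower in both, 4.23 and 20.1 from independent lists; r = 0.529, rho = 0.413).

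BMP4 ran the other way for many of these transcripts. With dissociation it shared the direction of 29.0% (23.2 to 35.3), with 164 transcripts opposite where independent lists give 21.8 (r = -0.133, rho = 0.0527). With Cerberus the share was 19.9% (14.6 to 26.1), with 161 opposite against 12.2 (r = -0.298, rho = -0.187). BMP4 and Wnt8 went the same way in 50.4% (41.8 to 58.9; 57 higher and 14 lower in both, 3.574 and 1.956 from independent lists). Chordin and Wnt8 did so in 78.3% (69.6 to 85.4; 28 higher and 62 lower in both, 1.247 and 3.934 from independent lists).

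Dissociation also shared the direction of most doubly changed transcripts with FGF8 (92.2%, 88.53 to 94.99), Xnr2 (86.2%, 83.3 to 88.8) and Wnt8 plus Xnr2 (85.0%, 82.0 to 87.6). For FGF8 81 were higher and 191 lower in both (4.54 and 15.5 from independent lists), for Xnr2 132 and 424 (14.7 and 60.8), and for Wnt8 plus Xnr2 115 and 444 (15.03 and 42.12). BMP4 shared the direction of 64.1% with FGF8 (56.9 to 70.8; 113 higher and 12 lower in both, 5.48 and 1.85 from independent lists) and of 81.0% with Xnr2 (76.2 to 85.2; 205 and 46, against 18.2 and 7.67).

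In 2 of these comparisons the treatments share a control library, which alone pushes ratios the same way. For Wnt8 and Cerberus, both set against control 3, 95.2% of doubly changed transcripts went the same way (92.64 to 97.02; 80 higher and 314 lower in both, 2.59 and 13.97 from independent lists), while simulated unchanged libraries gave 94.1% and 95.1% with a spread taken between all libraries and within control sets. The covariance of the ratios was 0.165 beside simulated values of 0.229 and 0.0982, so the sign of the difference depends on the spread assumed. Part of the excess may come from the shared control. For BMP4 and Chordin, both set against control 1, 22.2% went the same way (15.1 to 30.8; 91 opposite against 5.10 from independent lists, 19 higher and 7 lower in both against 2.37 and 1.66), where simulation gave 94.5% and 95.1%. The covariance was -0.00257 beside 0.221 and 0.0955. One library per control set cannot be split further.

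Of the 8 responses, those to dissociation and Cerberus had the highest correlations with the dorsal to ventral ratio. Across 13956 transcripts its Pearson r with the dissociation response was 0.555 (rho 0.394) and with Cerberus, across 13840, 0.567 (rho 0.314). It was 0.358 with Chordin (rho 0.234), 0.327 with Wnt8 (rho 0.263), 0.194 with FGF8 (rho 0.163), 0.2 with Xnr2 (rho 0.232), 0.305 with Wnt8 plus Xnr2 (rho 0.24) and -0.334 with BMP4 (rho -0.111). Of transcripts at least 4-fold higher dorsally, dissociation raised 36 of 43 at least 2-fold, Cerberus 34 of 41 and Chordin 24 of 33, whereas BMP4 raised 2 of 30 and lowered 17. Of those 4-fold higher ventrally, dissociation lowered 27 of 30 and Cerberus 25 of 29, while Chordin lowered 8 of 20 and raised 1, and BMP4 raised 16 of 25. These counts cover only transcripts that pass the filter in the caps. Without the minimum of 5 RPKM, 70 transcripts were at least 4-fold higher dorsally and 41 ventrally. As for the lists, the filter pushes the shares raised upward.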

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

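Tests on counting noise in control 1 and on the names of control set 4 were chosen after the results were seen. For 2 others the bounds were written first and the reading changed afterwards, as stated at each.

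A control library far from the other 3 was found for the mean of the endoderm list (6 members), which was 0.864 on the log2(RPKM + 1) scale in control 1 and 2.62 to 2.93 in controls 2 to 4. Its gap to the nearest control was 0.849 of the whole range, above the 95% critical value of Dixon's test for 4 samples. Of 20 items tested only this passed its critical value, and chance alone gives about 1 in 20.

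In data that the comparisons leave out, 902 transcript names stood over 1 RPKM in control 4 without a read in the 6 libraries of the full table, and 242 transcripts over 5 RPKM in controls 1 to 3 were not listed for control 4. A candidate explanation is that set 4 tables use other names for the same genes. Of the 830 of these names with a symbol, 250 (30.1%) had a partner of the same base symbol that was over 1 RPKM in controls 1 to 3 and not listed for control 4, against 216 of 8447 other names (2.56%). That goes with other names for part of them and leaves the others unaccounted for. No biological explanation was tested.

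Control 1 had lower values of BMP target, epidermis and ciliated cell genes than the other controls. Counting noise at low read numbers is argued against: over the 69 members with at least 100 reads in each of controls 1 to 3, the median log2 difference of control 1 was -1.043 (quartiles -2.058 to -0.147, 56 of 69 below 0). A shift of control 1 along the axis on which dissociated caps differ from controls stays open. The stated bound used 1 dissociation ratio, that of set 3, whose correlation with control 1 minus control 2 was 0.012 and counted against the shift, but control 1 minus control 4 gave 0.040 with set 3 and 0.435 with set 2, and control 1 minus control 3 gave 0.420 with set 2. Because these values disagree, the bound on 1 ratio was judged too narrow after they were seen. A biological difference between embryo batches was not tested.

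The responses to dissociation, Chordin and Cerberus ran the same way across transcripts, but not these alone. With no library shared, dissociation correlated at r = 0.529 with Wnt8, 0.490 with FGF8, 0.479 with Xnr2 and 0.435 with Wnt8 plus Xnr2. With BMP4 r was -0.133. Cap libraries may vary along this axis whatever the treatment. Differences between controls should then correlate with dissociation ratios of other sets as strongly as the lower of the Chordin and Cerberus correlations, 0.448. The highest of 9 such values was 0.435, which by the bound as written counted against it. The margin is small beside the SD of the 9 values, 0.177, a comparison added after they were seen. Variation between cap libraries and a shared treatment effect thus cannot be told apart with 1 library per injection. The biological reading, less BMP signalling in these caps, was not tested beyond the lists.

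For the 50 calls of dissociation, the 10 splits of the 6 libraries are too few for a share under 0.05. In 1 of the 10, the real one, that many calls were reached, and the highest other count was 10, with control 1, dissociated 1 and dissociated 2 against the rest, a split that parts 1 pair. The 3 other splits that part all 3 pairs gave 0 calls by limma.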

How the results depend on the processing

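Median scaling, voom on recovered reads, the kept names of control set 4 and the minimum of 5 RPKM across transcripts were chosen after the results were seen. Over all alternatives run, of 1280 values of named genes 877 kept their call, 403 lost it and 0 reversed. With summed copies 79 of the 84 gene lists called passed and 5 did not, which the report names, and with an estimated correlation 39 did. Of the 84, 0 were tested in the other direction with an estimated correlation or with summed copies. With the block, 1 was, the stress list after Chordin, which lost its call, and the median of the neural crest list after Wnt8 turned from 0.76 to -0.07. Where a count moved, the cause was not tested, except that leaving out a library or summing copies leaves less to test. The count-based alternatives written beforehand were not run, since the files hold no counts. Leaving out the filter changed nothing for BMP4, FGF8, Xnr2 and Wnt8 plus Xnr2, whose tables hold no transcript below it. Depth limits the 1 to 1 ratios of weak transcripts, such as SFRP5 with 4 ventral reads.

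With the control set as a block (the pairing of the control numbers), calls went from 50 to 239 for dissociation, 69 to 44 for BMP4, 2 to 1 for Chordin, 12 to 0 for Wnt8 (474 at an unadjusted p under 0.05 by limma), 12 to 6 for Cerberus and 24 to 1 for FGF8. For Xnr2 and Wnt8 plus Xnr2 they were 508 and 457, within 1.5 times of 611 and 561. Gene lists called were 95 of 136 with the block and 84 without, 82 of them shared. The block changed no other call of a list than those given in the report.

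Without a filter on low values, dissociation had 0 calls by limma (36170 transcripts tested, 2599 at an unadjusted p under 0.05), Chordin 1 and Cerberus 1. A pseudocount of 0.1 gave 16 for BMP4, 1 for Chordin, 0 for Wnt8 (280 at an unadjusted p under 0.05 by limma), 5 for Cerberus and 1 for FGF8. A pseudocount of 5 gave 22 for dissociation, 30 for Wnt8 and 59 for FGF8. Summed L and S copies gave 1 for Chordin, 2 for Wnt8 and 10 for FGF8. Quantile normalization gave 37 for FGF8 and median scaling 6 for Cerberus. With control 4 added, dissociation had 209 calls.

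Leaving out 1 library in turn gave 0 (without control 3 or without dissociated 2; 966 and 985 at an unadjusted p under 0.05 by limma) to 375 calls for dissociation (without control 1), 53 to 116 for BMP4, 1 to 76 for Chordin, 1 to 29 for Wnt8, 1 to 87 for Cerberus and 8 to 66 for FGF8. The highest value came without control 1 in each of these except FGF8, where it came without control 4. For Xnr2 and Wnt8 plus Xnr2 the ranges were 495 to 779 and 463 to 751.

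On recovered reads, voom called 4 for dissociation, 29 for BMP4, 0 for Wnt8 (277 at an unadjusted p under 0.05) and 4 for Cerberus. Voom fits of BMP4, Chordin, Wnt8 and Cerberus left out control 4, without which limma called 59, 1, 1 and 3. For these, the part of voom alone was not tested. With the block, voom called 511 for dissociation, 0 for BMP4 (485 at an unadjusted p under 0.05), 1 for Chordin, 3 for Wnt8, 34 for Cerberus, 0 for FGF8 (463 at an unadjusted p under 0.05), 353 for Xnr2 and 368 for Wnt8 plus Xnr2. With the names of control set 4 kept, FGF8 had 10 calls, 7 of them shared with the 24, Xnr2 613 and Wnt8 plus Xnr2 580.

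In the 1 to 1 comparisons, Wnt8 plus Xnr2 against Xnr2 gave 36 transcripts at 4-fold, 450 at 2-fold and 7 at 8-fold, and dorsal against ventral 106, 437 and 26. At 4-fold, the share of transcripts going the same way was 100% for dissociation with Chordin and with Cerberus, for Chordin with Cerberus and for Wnt8 with Cerberus, 97.96% for dissociation with Wnt8 and 91.67% for Chordin with Wnt8. It was 8.696% for dissociation with BMP4, 10% for BMP4 with Chordin and 9.524% for BMP4 with Cerberus. With a minimum of 5 RPKM, the correlation with the dorsal to ventral ratio was 0.575 for dissociation, -0.356 for BMP4, 0.391 for Chordin and 0.602 for Cerberus.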

Other observations

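The comparison of deposited ratios and the grouping of genes below were chosen after the results were seen.

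Endogenous chordin transcripts were present in caps that received Xnr2. CHRD (Xelaev18029538m) read 169 RPKM after Xnr2 and 212 after Wnt8 plus Xnr2, against 0.285 in control 4, and 120 in the dorsal and 3.33 in the ventral part of the embryo. The names chrd.1.L and chrd.2.L read 124 and 90.6 RPKM after Xnr2 and 106 and 124 after both mRNAs. The cer1.S transcript read 216 RPKM dorsally and 59.7 ventrally, and wnt8a.L 54.2 and 107.

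Some transcripts rose after both Wnt8 and FGF8, without the block and in tests that share controls 1 to 4. The transcript pnhd.S rose by 3.40 ± 0.281 after Wnt8 (adjusted p = 0.00709 by limma) and by 3.95 ± 0.296 after FGF8 (adjusted p = 0.00192), and hoxd1.S by 3.36 and 3.59. Neither was called with the control set as a block, at adjusted p = 0.119 after Wnt8 and 0.0778 after FGF8 for pnhd.S and 0.293 and 0.269 for hoxd1.S. Against the matched controls, which are 3 for Wnt8 and 4 for FGF8, of transcripts at least 2-fold changed by both, 83 were higher and 134 lower in both, where independent lists give 2.54 and 7.11, and 8 went opposite ways (r = 0.443, rho = 0.182 over 13711 transcripts).

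The authors' deposited table that sets responses side by side lists 17317 transcripts. Its Cerberus fold lay within 0.1% of Cerberus over control 2 for 16588 of the 16588 transcripts that could be compared, and within 0.1% of Cerberus over control 3 for 17 of 16605, although the labels name control 3 as the control of Cerberus.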
